A study of Homo sapiens with 4 samples.

How the data were processed

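Total RNA from LPS-treated THP-1 macrophages was amplified as cDNA, labelled with Cy3 and hybridised to a 1-colour Agilent human array, 1 array per sample, per the labels' protocols. The scanner files were made with Agilent Feature Extraction 11.5.1.1, per the submitters' processing notes and the file headers, which also state a 1-colour protocol. Each file holds linear intensity values per spot, per the file headers: a processed signal, corrected for background within the array and not normalised between arrays, the raw median spot and local background intensity, and flags for outliers, saturation and signal well above background. The authors also deposited a table of processed intensity values. Each of its columns equalled the processed signal of 1 array times a constant (4.35 and 4.29 for control replicates 1 and 2, 4.68 and 4.24 for miR-204-3p replicates 1 and 2), so it is linear, is not centred by gene and runs in the same direction; how the constants were set stays unknown. The medians of its columns were 80.1, 76.5, 81.5 and 78.7 in the same order.

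Groups came from the sample titles. Control spots and spots with an outlier flag (97 to 136 per array) were left out, and the 10 spots of each of 300 repeated probes were averaged. The main values were log2 of the processed signal minus the array's 75th percentile of it over non-control probes. A probe was tested if it was well above background on both arrays of at least 1 group, which left 27512 of 58201 probes. Depth has no counterpart on these arrays. The median processed signal was 17.4 to 18.6 per array, the 75th percentile 236 to 255, and repeated probes had a median coefficient of variation of 4.22% to 4.43% within an array. The spike-in controls had slopes of 0.995 to 1.01.

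The files give accessions in place of gene names. These were matched without version to a RefSeq gene table of assembly GRCh38.p14, which named 94.0% of the 33080 probes with a RefSeq accession. In all 31104 probes had 1 symbol, 0 had several and 27097 had none, for 22439 symbols. The array's own annotation is on another build, so no coordinates are given. For each gene the tested probe with the highest mean signal was kept, over 14945 genes, of which 3725 had more than 1 tested probe.

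The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with 1 variance prior, two-sided, Benjamini-Hochberg adjustment, threshold 0.05), with no replicate block. In the text a log2 fold change is miR-204-3p minus control. A probe not well above background on any array of a group has only a bound there. Its fold is given as "at least", from the bright group's mean over the dim group's mean of, per array, the higher of the dim probe's signal and the lowest signal among probes well above background. Of 13 gene lists, fixed from textbook knowledge before the data were examined, each was tested with camera at a preset correlation of 0.01, with adjustment over the 13 lists; camera with an estimated correlation and fry were alternatives, with the latter's p given for a shift 1 way. None of the 3 called lists held with an estimated correlation, and the cytokine and interferon lists held in fry. The counts adjusted over the list alone use the same limma p-values. List medians were also set against 10000 random lists matched on mean signal in 20 bins. In addition to the 13 lists, 3 lists of further interferon-induced genes, further sterol-regulated genes and LXR targets were written after the first results and before the values of their genes were seen.

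The genes named in the text were set by a rule fixed before the data were examined. It takes 14 genes of the PI3K, TLR4 and cytokine pathways whatever their values. It takes the 10 largest rises and 10 largest falls past the threshold whose arrays do not overlap and whose probe is well above background in the brighter group, filled up by the largest moderated t where fewer pass. It takes up to 4 members per list, those past the threshold first and then the brightest. Loci with no official name were skipped, and 1 Y-linked locus is not reported here. The list members past the threshold when adjusted over the list alone, the dimmer PIK3CD probe, PIK3AP1 and the genes named in the closing section were chosen after their values were seen.

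The procedure was tested on simulated data for miR-204-3p against control, with the mean signal of the 14945 genes, a spread drawn from the fitted relation of variance to intensity, and 200 genes changed, 20 times over. With 1 variance prior, 0.0746% of changes of 0.3 on the log2 scale were recovered, 0.746% of those of 0.5 and 70.2% of those of 1. With a prior that follows intensity the shares were 36.9%, 69.9% and 89.5%, on data made with that same relation. The trend also called more unchanged genes, 6.05 per simulation against 1.75 with 1 prior. A list of 30 genes shifted by -0.1 was called by camera in 20 of 20 simulations, and 0 of 240 unshifted lists were called; the simulated genes were independent of each other.

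Alternatives were normexp background correction (offset 50), quantile normalisation, median centring, no filter on dim probes or a filter on all 4 arrays, an intensity trend or a robust prior in eBayes, keeping flagged spots, the replicate number as a block, leaving out each array in turn, the slide as a block, the authors' deposited values, the mean of a gene's probes, and a threshold that adds an absolute log2 fold change of 1. The normexp alternative used the median spot intensity, because the files hold no mean spot intensity. Its offset draws the values of dim probes towards 0. Slide and scan gave the same batches. The first held both controls and miR-204-3p replicate 1, and the second miR-204-3p replicate 2 alone, so that the slide as a block equals leaving out that array. A planned comparison of genes with and without a seed match to miR-204-3p in their 3' UTR was not run, because no sequence was used here.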

Results

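Gene expression was measured in macrophages derived from THP-1, a human monocytic leukaemia cell line, after 18 hours with 100 ng/ml of lipopolysaccharide (LPS), the bacterial cell wall component that signals through TLR4. The 4 samples formed 2 groups, a control group and a group given the microRNA miR-204-3p, with 2 samples in each. Each sample was hybridised alone to a 1-colour Agilent expression array. How the microRNA was delivered, and whether the 2 samples of a group came from separate cultures, is not given in the sources used here. The limma p-values of single genes therefore measure the spread between these samples, which may be technical. Camera p-values at the preset correlation compare list members with other genes on the same 4 arrays. They do not treat the samples as the replicates. Between 30273 and 31281 of the 60901 non-control spots on each array were well above background (49.7% to 51.4%), and 0 spots were saturated. Across the 14945 genes tested, Pearson's r between the log2 signals of the 2 arrays was 0.998 in either group, and 0.997 for each pair of 1 control and 1 miR-204-3p array; genes are not independent replicates. The number of arrays limits the precision of every value that follows.

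The comparison of miR-204-3p with control asked how expression after LPS differs with the microRNA. Of particular interest were PI3K gamma signalling and the cytokines downstream of TLR4, which the study's title names. All 4 samples had LPS, so an altered response to LPS cannot be told from a difference present without it. Among 30 measured LPS-induced cytokines and chemokines, IL12B, the subunit shared by interleukins 12 and 23, showed the largest difference in the processed signal, while with normexp on the median spot intensity CXCL10 (-0.51 on the log2 scale) lay further from 0 than IL12B (-0.45). Its normalised log2 signal was -0.66 ± 0.01 (SD, n = 2) in controls and -1.27 ± 0.03 (SD, n = 2) with miR-204-3p, 1.52-fold lower. The interferon-inducible chemokines CXCL10 and CXCL11 were 1.40-fold and 1.38-fold lower, the monocyte chemoattractants CCL8 and CCL2 1.33-fold and 1.22-fold lower, and IL6 1.21-fold lower. PIK3CG, which encodes the catalytic subunit of PI3K gamma, was 1.24-fold lower, and a group of interferon-response genes lay slightly lower together. Genes of cholesterol synthesis lay slightly higher together. With an estimated correlation between genes, a version that rests on the few residual degrees of freedom of the arrays, neither list passed in camera (adjusted p = 0.273 and 0.352). The interferon list's estimate (-0.00088) was below the preset 0.01, so correlation did not remove that call. The cholesterol list's was 0.065, and whether correlation or the few degrees of freedom removed its call was not tested. The cholesterol list did not pass in fry (adjusted p = 0.135). In the limma test with Benjamini-Hochberg adjustment over all genes, no single gene passed with 1 variance prior, and 115 passed with a prior that follows signal intensity. The sentences on single genes give measured values unless a test is named.

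**Figure D1:**
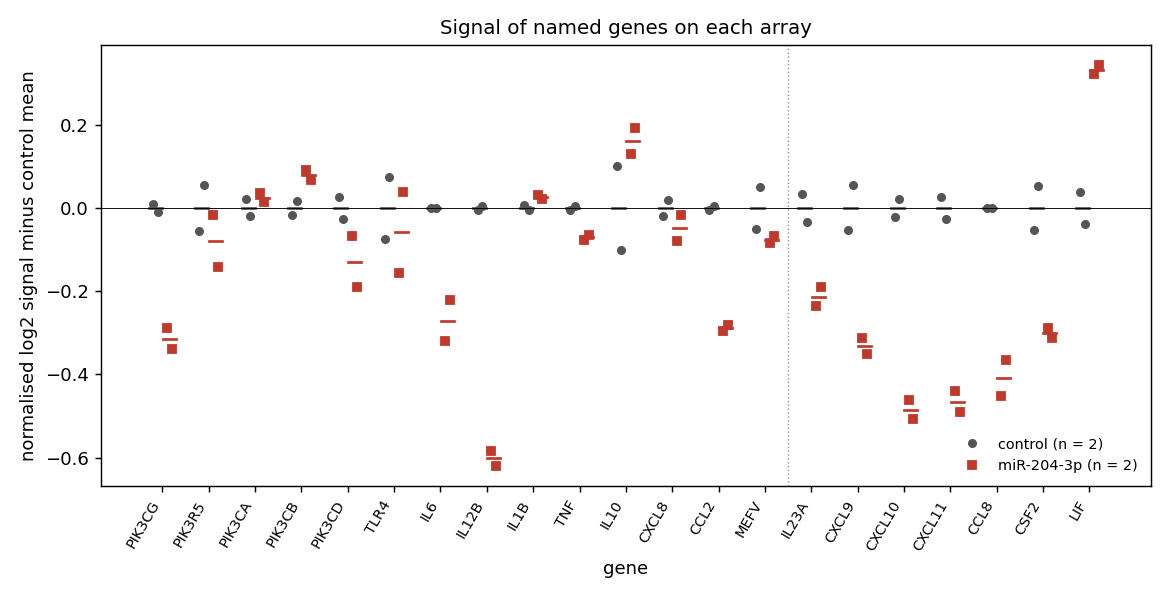
Normalised log2 signal of each array minus the control mean of the gene (y axis) for 21 genes (x axis), with control arrays as grey circles, miR-204-3p arrays as red squares and group means as short bars (n = 2 per group). The 14 genes left of the dotted line were fixed before the data were examined, and the 7 to its right are further cytokines and chemokines past the threshold when adjusted over their list alone. Both miR-204-3p arrays lie below both control arrays for PIK3CG, IL6, IL12B and CCL2, while TLR4 and CXCL8 overlap.

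The LPS-induced cytokines and chemokines had a median log2 fold change (miR-204-3p over control) of -0.080, and 22 of the 30 measured members lay below 0. None passed the adjustment over all genes. Adjusted over the list alone with 1 variance prior, 9 fell and 1 rose, and 20 did not pass. The 9 that fell were IL12B (-0.60), CXCL10 (-0.49), CXCL11 (-0.47), CCL8 (-0.41), CXCL9 (-0.33), CSF2 (-0.30), CCL2 (-0.29), IL6 (-0.27) and IL23A (-0.21). LIF, a cytokine of the interleukin 6 family, rose by 0.33 on the log2 scale. Adjusted over the list alone with a variance prior that follows signal intensity, 10 fell and 5 rose. The 5 were LIF, CSF3 (0.32), OSM (0.27), CXCL2 (0.17) and CXCL3 (0.13), so the list was mixed. Over all genes with that prior, LIF rose and 7 of the 9 named above, all but CSF2 and IL23A, fell. Of these 8, CXCL10, CXCL11 and CCL8 also passed whichever of the 4 arrays was left out, IL12B, CCL2 and CXCL9 passed in 1 of the 4 such fits, and IL6 and LIF in 0. In each such fit, here and below, 1 group is a single array and the spread within groups comes from the other group alone, so these passes do not replace replicates. With normexp on the median spot intensity the value of CSF2 was -0.20. Among the brightest members, CCL3 had a log2 fold change of -0.13 (SE 0.05), CCL5 one of -0.08 (SE 0.05), and IL1B one of 0.03 (SE 0.05, and 0.0078 with normexp), all with adjusted p over all genes above 0.05. TNF was at -0.07, CXCL8 at -0.05 and the anti-inflammatory cytokine IL10 at 0.16 (0.08 with normexp). For 17 members both miR-204-3p arrays lay below both controls and for 8 both lay above. Chance puts 33.3% of genes in either of these positions. Over all 14945 genes tested the share was 41.0%, with 2955 below and 3172 above. The list as a whole was lower than other genes in the camera set test with a preset correlation (adjusted p = 0.000348 over 13 lists). With an estimated correlation it was not past the threshold (adjusted p = 0.302), though the estimate (-0.024) was below the preset 0.01. Fry, which asks whether the members move one way on balance, gave an adjusted p of 0.00885. The array with miR-204-3p replicate 2 was the only one on a second slide, and within the first slide the list's median was -0.084.

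PIK3CG had a normalised log2 signal of 3.24 ± 0.01 (SD, n = 2) in controls and 2.93 ± 0.04 (SD, n = 2) with miR-204-3p, a log2 fold change of -0.31 (SE 0.05, limma adjusted p = 0.389). The difference was larger than the spread between replicates in either group, and 380 of the 14945 genes had a more negative fold change. Within the first slide the value was -0.29. With a variance prior that follows signal intensity, the adjusted p of PIK3CG was 0.0204, and between 0.0479 and 0.115 when 1 of the 4 arrays was left out, under the threshold only without miR-204-3p replicate 1. Its regulatory partner PIK3R5 was at -0.08, and the other catalytic subunits PIK3CD, PIK3CA and PIK3CB were at -0.13, 0.02 and 0.08 (-0.15, 0.0066 and 0.039 with normexp), none past the threshold. A dimmer PIK3CD probe gave -0.40. The most negative value in the PI3K and AKT list was that of PIK3AP1, a PI3K adaptor gene, at -0.34 (SE 0.06), though with normexp PIK3AP1 was at -0.26 and PIK3CG at -0.33. PIK3AP1 had an adjusted p of 0.0586 over the list alone, the same as for PIK3CG, and of 0.0787 over all genes with the intensity trend. Of the 28 measured genes of PI3K and AKT signalling, 0 passed over all genes and 0 adjusted over the list alone, and the list's median was 0.00, its mean -0.02 and its camera direction down (adjusted p = 0.719). Among its brightest members, the phosphatase gene INPP5D was at -0.10, PIK3R2 at 0.06 and GSK3A at 0.06. Of 32 measured genes of the TLR4 receptor and NF-kB signalling, 0 passed in either adjustment. TLR4 was at -0.06 (SE 0.10), with overlapping groups, and the inhibitor gene NFKBIA was also at -0.06 (SE 0.05). The median of that list was -0.03 (camera adjusted p = 0.164).

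Type I interferon response genes lay lower with miR-204-3p. Of the 31 measured members 30 had a log2 fold change below 0, and for 24 both miR-204-3p arrays lay below both controls. None passed individually, over all genes or adjusted over the list alone, and the differences were small, with a median of -0.11 and a range of -0.29 to 0.13. The brightest members, the antiviral genes ISG15, IFITM3, IFI6 and IFITM1, were at -0.05, -0.02, 0.13 and -0.04; IFITM3 changed sign with quantile normalisation (0.02). As a list they were lower than other genes in camera (adjusted p = 3.41e-08), not with an estimated correlation (adjusted p = 0.273), and fry gave an adjusted p of 0.0120. With the prior that follows intensity, IFIT2 (-0.29) and HERC5 (-0.25) fell over all genes, and passed in 1 and 0 of the 4 fits that leave out an array. Within the first slide the median was -0.10. None of these 31 genes is in the cytokine list. That list does hold the interferon-inducible CXCL10 and CXCL11, so the shifts of the lists may not be separate.

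Cholesterol synthesis genes lay higher with miR-204-3p. Of 22 measured members 21 had a log2 fold change above 0, and for 17 both miR-204-3p arrays lay above both controls. None passed individually, over all genes or adjusted over the list alone. The median was 0.10 and the values ran from -0.10 to 0.35. Among the brightest members, FDFT1, which encodes squalene synthase, was at 0.16 (SE 0.05, and 0.087 with normexp), NSDHL at 0.12 (SE 0.05) and FDPS at 0.10 (SE 0.05), while SQLE, which encodes squalene epoxidase, was at 0.01 (SE 0.06) and changed sign with median centring (-0.01). Camera placed the list above other genes (adjusted p = 2.64e-05). That call was lost with an estimated correlation (adjusted p = 0.352) and in fry (adjusted p = 0.135). Within the first slide the median was 0.095.

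**Figure D2:**
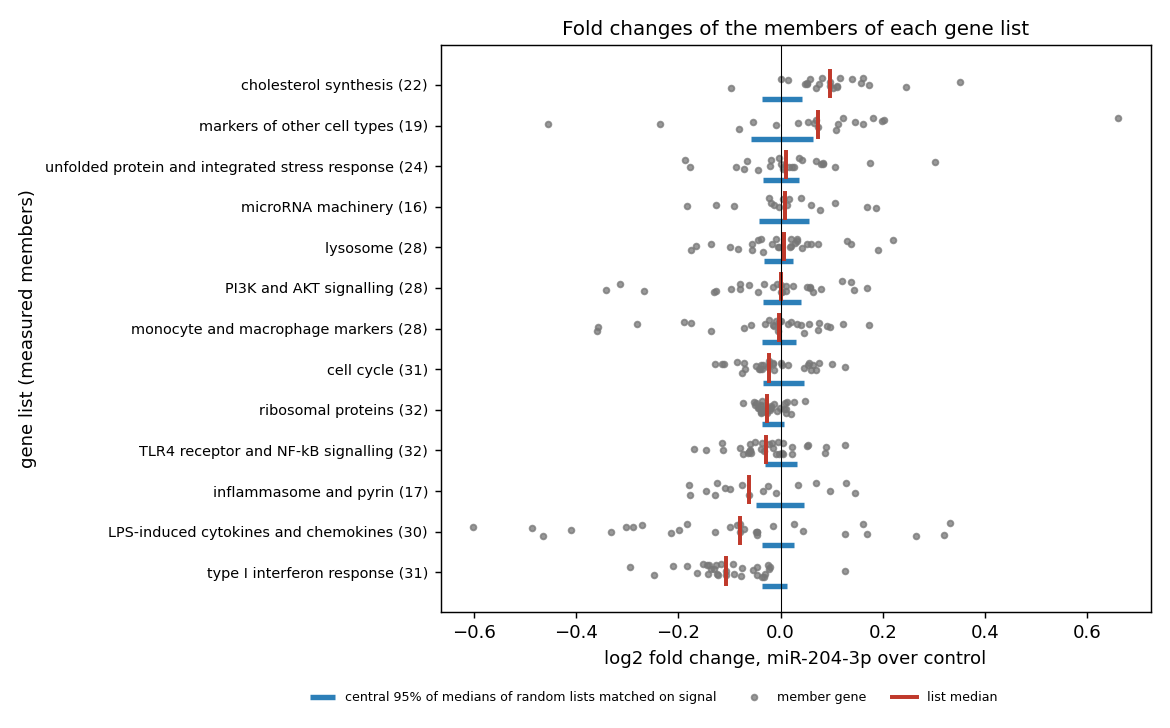
Log2 fold change, miR-204-3p over control (x axis), of each measured member (grey points) of 13 gene lists (y axis, number of measured members in brackets), with the list median (red line) and the central 95% of the medians of 10000 random lists matched on mean signal (blue bar). The medians of the interferon list (-0.11), the cytokine list (-0.080) and the cholesterol list (0.10) lie outside their blue bars, as do those of the inflammasome list (-0.06) and the markers of other cell types (0.07).

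With 1 variance prior the other 8 lists held no member past the threshold, over all genes or adjusted over the list alone. Camera called none of them in the main setting. With the prior that follows intensity 1 member, TRIB3 (0.30), rose over all genes. Adjusted over the list alone with that prior, 2 inflammasome genes fell (NLRP3 and P2RX7, both -0.18). So did 3 macrophage markers, CD80 (-0.28), MSR1 (-0.19) and CD40 (-0.18). Of the stress genes 2 rose, TRIB3 and PDIA4 (0.18), and 2 fell, ATF3 (-0.18) and ATF5 (-0.19). Of 17 measured inflammasome and pyrin genes, 12 lay below 0, with a median of -0.06 (camera adjusted p = 0.0746, and 0.689 with an estimated correlation). It was past the threshold with the intensity trend (adjusted p = 0.0432) and with normexp on the median spot intensity (median -0.085, adjusted p = 0.0230). MEFV, the gene of pyrin that is mutated in familial Mediterranean fever, was at -0.08 (SE 0.06, and -0.13 with normexp), and CASP1 and CASP4, which encode inflammatory caspases, were at -0.15 and -0.11. Markers of other cell types had a median of 0.07 over 19 measured genes (camera adjusted p = 0.0746, and 0.466 with an estimated correlation), and of 0.13 within the first slide (adjusted p = 0.00652, with a single miR-204-3p array and the spread from the 2 controls alone). It was past the threshold with the intensity trend (adjusted p = 0.0436) and with normexp (adjusted p = 0.0133). Its brightest members were the granulocyte gene AZU1 at 0.11, PECAM1 at 0.07, GNLY at 0.07 and CD79A at -0.05, and its median moved opposite to the cytokine and interferon lists and with the cholesterol list. The monocyte and macrophage markers (28 measured, with MMP9 at 0.04 and CSF1R at -0.01) had a median of 0.00, and the 31 cell cycle genes, with MCM7 at 0.06 and MCM3 at -0.04, one of -0.02. The medians were 0.01 for 24 genes of the unfolded protein and integrated stress response, 0.01 for 28 lysosome genes, -0.03 for 32 ribosomal protein genes and 0.01 for 16 genes of the microRNA machinery. Of these, the stress gene ATF3 was at -0.18, DROSHA, the nuclear microRNA processing enzyme, at -0.18 and AGO2 at -0.09. For the lysosome list camera's direction was down (adjusted p = 0.986), against the sign of its median. Under other settings the medians of all lists named in this paragraph, except those of the inflammasome genes and the markers of other cell types, crossed 0, and those of the lysosome, microRNA machinery, macrophage, stress and ribosomal lists did so with another scaling between arrays alone.

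The genes with the largest moderated t whose arrays did not overlap were also examined, 10 in each direction, with limma adjusted p = 0.389 for all of them. With the prior that follows intensity, 11 of the 20 passed. MMP13, DHRS9, ITGB8, STK25 and ADGRG1 did so also in all 4 fits that leave out an array, CSAG1 and CH25H in 3, IL12B and CD5 in 1, and CD69 and XKR5 in 0. On the lower side, beside IL12B, were the collagenase gene MMP13 (-0.76, 1.69-fold), DHRS9 (-0.62, 1.54-fold), CSAG1 (-0.58), the lymphocyte activation marker CD69 (-0.55), FRAS1 (-0.53), the integrin gene ITGB8 (-0.50), CH25H, which encodes cholesterol 25-hydroxylase (-0.47, 1.39-fold), and XKR5 (-0.67). EPB41L4A-DT was not well above background on either miR-204-3p array and was at least 1.61-fold lower there. On the higher side, STK25 was at 0.61 (1.53-fold) and the adhesion receptor gene ADGRG1 at 0.46 (1.37-fold), and the remaining genes were dim. KLHL30 was at 0.61, DDX11L2, which has near-identical copies and is therefore uncertain, at 0.55, TWIST2 at 0.55 and ENHO at 0.41. CD5, ZNF436-AS1, C1QTNF5 and NR1I3 were not well above background on either control array, and were at least 1.68-fold, 1.65-fold, 1.61-fold and 1.47-fold higher with miR-204-3p. These bounds hold for the processed signal alone, since with normexp the values were 0.51, 0.29, 0.29 and 0.14, and -0.20 for EPB41L4A-DT, all smaller than the bounds. With normexp KLHL30, DDX11L2, TWIST2 and ENHO were at 0.25, 0.17, 0.24 and 0.18, and FRAS1, XKR5 and CD69 at -0.23, -0.34 and -0.34, none past the threshold. Past it over all genes with normexp were MMP13 (-0.72), DHRS9 (-0.57), CSAG1 (-0.47), ITGB8 (-0.46), IL12B (-0.45) and STK25 (0.59).

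**Figure D3:**
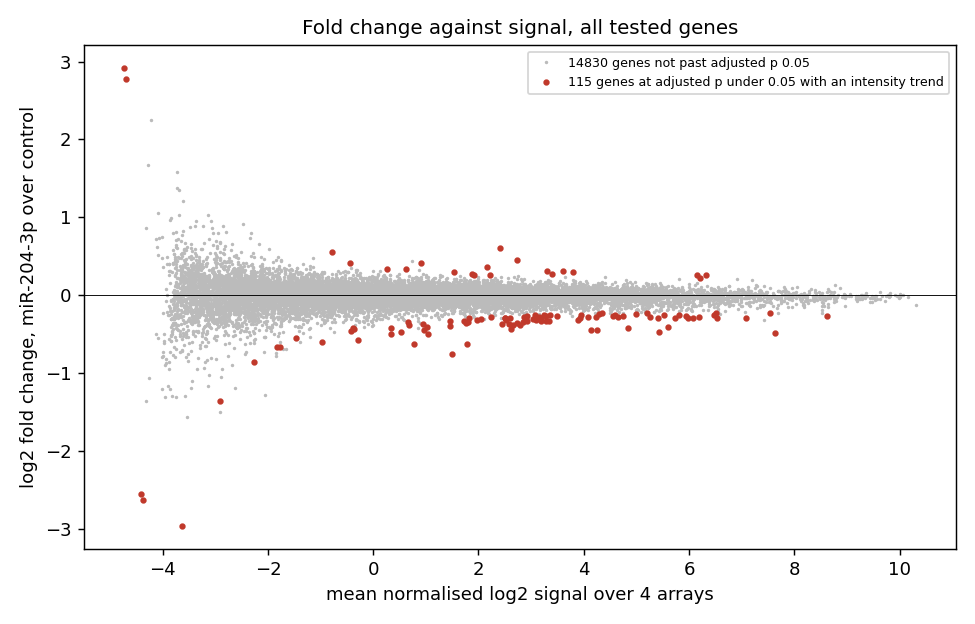
Log2 fold change, miR-204-3p over control (y axis), against the mean normalised log2 signal over the 4 arrays (x axis) for the 14945 genes tested. Red points are the 115 genes at adjusted p under 0.05 when the variance prior follows intensity, 21 higher and 94 lower, and grey points are all others. The spread widens at low signal, where some points stand for genes measured in 1 group only.

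Over all genes, limma with 1 variance prior called 0 genes higher and 0 lower. At an unadjusted p under 0.05 there were 595 higher and 795 lower, where 747 are expected by chance in all, and the smallest adjusted p was 0.389. Among the 27512 probes, 0 were higher and 2 lower, both for noncoding transcripts with no gene symbol, which the files name lnc-ATMIN-3 and lnc-SPTBN5-2 and which were singled out after their values were seen. Neither was well above background with miR-204-3p, where they were at least 3.36-fold lower (adjusted p = 0.0103) and at least 1.44-fold lower (adjusted p = 0.0182). Both calls were lost with normexp and when any 1 array was left out. With a variance prior that follows intensity, 21 genes rose and 94 fell, and with normexp on the median spot intensity 2 rose and 16 fell. The former counts became 9 and 58 without control replicate 1, 3 and 28 without control replicate 2, 16 and 42 without miR-204-3p replicate 1, and 9 and 18 without miR-204-3p replicate 2. Of the genes called in these 4 fits, 42 of 67, 23 of 31, 30 of 58 and 16 of 27 were among the 115, and 13 of the 115 passed in all 4 and 60 in none. By exact permutation, 2 arrays against 2 cannot give a two-sided p below 0.333 for a single gene.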

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

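The trend settings that are combined with a second choice, and the settings that leave out 1 array under the trend, were chosen after seeing the data. The counts of calls moved with the variance model and with normexp, which changes both the background method and the input, from processed to raw median intensity, so its effect cannot be put down to either. With an intensity trend 2 probes were higher and 15 lower, and 21 genes higher and 94 lower; with normexp the genes were 2 and 16, 17 of these 18 being among the 115 trend calls, and 0 probes were lower. The 2 lower probes became 0 with no filter, with the filter on all 4 arrays, with the slide as a block, in the replicate block fit and when 1 array was left out (0 in each case). The trend gave 9 and 58, 3 and 28, 16 and 42, and 9 and 18 genes higher and lower without control replicates 1 and 2 and miR-204-3p replicates 1 and 2 in turn, with 42 of 67, 23 of 31, 30 of 58 and 16 of 27 among the 115, and 10 and 77 with the replicate block, and 6 and 59 with normexp. In the simulation the trend recovered more small changes and called more unchanged genes; beyond that the cause was not tested. The fold change of PIK3CG kept its sign in every setting run (-0.34 to -0.29). Its adjusted p ranged from 0.0204 to 0.822 over the planned settings and was under the threshold with the trend (-0.31), with the trend and replicate block (-0.31) and with the trend and normexp (-0.33). Without 1 array under the trend its value ran from -0.34 to -0.29, and it passed only without miR-204-3p replicate 1 (-0.34).

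The replicate numbers do not establish pairs, since the deviations of same-numbered arrays correlated at 0.04 across genes; the replicate block changed no other call. The cytokine, interferon and cholesterol medians (-0.080, -0.11 and 0.097) kept sign and side of the threshold in every other planned setting, with ranges of -0.10 to -0.06, -0.13 to -0.08 and 0.07 to 0.11, but with an estimated correlation none passed (adjusted p = 0.302, 0.273 and 0.352), and in fry the cholesterol list did not (0.097, adjusted p = 0.135). Among 1323 values of the other 83 named genes, 19 of 13 genes newly passed and 53 of 20 genes crossed 0 without passing, at most 0.06 from it. Among 180 values of the other 10 lists, 6 newly passed, of the inflammasome list and the markers of other cell types, and 25 of 7 lists crossed 0, at most 0.02 from it. With normexp 40 of 84 named genes moved by over 1.5 times or changed sign, most of them near 0, and 0 of these 40 passed. No called value reversed. The seed match comparison and its alternatives were not run. About 50% of spots were well above background. Changes of tested genes that were dim in 1 group are only bounded. Probes not well above background on both arrays of either group were not tested in the main setting.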

Other observations

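The comparisons of the fixed lists with matched random lists, the bootstrap intervals, the splits of the arrays, the test of bright probes and the reading of the first-slide medians as a test of the slide were chosen after the results were seen. The fits within the first slide and with an intensity trend were planned, and the predictions for the further interferon-induced genes, the further sterol-regulated genes and the LXR targets were written before their values were seen. A set of 20 further interferon-induced genes, none of them in the lists fixed in advance, had a median log2 fold change of -0.19. For 19 of them both miR-204-3p arrays lay below both controls. None passed over all genes with 1 variance prior, while adjusted over the list alone 10 fell. With an intensity trend 5 fell over all genes, GBP1 (-0.28), GBP2 (-0.30), GBP4 (-0.29), IDO1 (-0.23) and TNFSF10 (-0.28), which encode guanylate-binding proteins, a tryptophan-degrading enzyme and the death ligand TRAIL. When 1 of the 4 arrays was left out, GBP4 passed in 1 of the 4 fits and the other 4 genes in 0.

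The interferon list lay lower by a median of -0.11. Random lists matched on signal had medians of -0.04 to 0.01 (central 95%), and with quantile normalisation the interferon list's median was -0.082. This argues against scaling or signal level as its whole source. Matched genes were drawn independently, so their range does not allow for members that vary together. Within the first slide, with 1 miR-204-3p array, the median was -0.10 (bootstrap interval over members -0.12 to -0.07), which argues against the second slide as its source. This interval and those below resample genes. They do not allow for members that vary together or for the spread between arrays. Of the 3 splits of the 4 arrays into 2 and 2, 1 gave a median as large, the real one, with 0.011 as the largest of the others, and 3 splits are too few for a share under 0.05. Lower interferon signalling is a candidate explanation, since the further interferon-induced genes also lay below matched lists (-0.19 against -0.04 to 0.03). Both lists were read from the same 4 arrays, so the second does not repeat the comparison, and chance stays open.

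The cytokine list lay lower by a median of -0.080, outside the -0.04 to 0.03 of matched random lists. With quantile normalisation its median was -0.058. This argues against scaling or signal level as its whole source, though the matched range does not allow for members that vary together. Within the first slide the median was -0.084, but members went both ways and the interval (-0.22 to -0.0036) does not exclude that part of the shift may come from the slide. Compression of bright probes, which could hide changes of members such as IL1B, stays open, with a Spearman rho of -0.217 between signal and absolute change across 30 genes, which are not independent (bootstrap interval -0.535 to 0.153). Of the 3 splits 1 gave a median as large, the real one, with -0.0016 as the largest of the others, again too few to give a share under 0.05.

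The cholesterol list lay higher by a median of 0.097, against -0.036 to 0.042 for matched lists, and by 0.098 with quantile normalisation. This argues against scaling or signal level as its whole source. The matched range does not allow for members that vary together. Replicates 1 against replicates 2 gave a list median of 0.045, for which no matched range was made. Within the first slide the list's median was 0.095 (interval 0.04 to 0.11), which excludes 0, though part of the shift may come from the slide. Of the 3 splits only the real one (1) gave a median as large, with 0.045 as the largest of the others, too few for a share under 0.05. A sterol-regulated programme may contribute, since the 13 further sterol-regulated genes had a median of 0.080 against -0.05 to 0.06 in matched lists, but its bootstrap interval (0.034 to 0.096) reaches into that range and 0 of the genes passed over all genes or adjusted over the list alone. CH25H, whose product 25-hydroxycholesterol restrains sterol synthesis and activates LXR, was at -0.47, so less of it could be involved. In that case the 10 LXR targets were predicted to lie below matched lists. They did not, with a median of 0.042 against -0.063 to 0.054 in matched lists, so the prediction was not met. The bootstrap interval of -0.15 to 0.10 is wider than that range, so a lower median is not excluded.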
